A study of Arabidopsis thaliana with 14 samples.

How the data were processed

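Transcript levels were measured in roots of 12-day-old Arabidopsis thaliana plants (ecotype Col-0) with the Affymetrix ATH1 array, a 1-colour oligonucleotide array that reads each transcript with a set of short probes. Per the labels' protocols, plants grew on solid medium with 100 µM boron for 10 days and were then moved to 0.3 or 100 µM boric acid for 2 days, and total RNA was extracted with a column kit. The 14 arrays hold 7 genotypes at both boron levels, with 1 array per genotype and level. The genotypes were wild type, the single mutants nip5;1, bor1 and bor2, and the double mutants nip5;1 bor1, nip5;1 bor2 and nip5;1 nip6;1.

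The deposited values are intensity values on a linear scale, made by the authors with MAS5 per the submitters' processing notes; the version and settings are not given in the sources used here. The mean of each array after trimming 2% at each end was 500.04 signal units, so the arrays already stood on a shared scale, and the array medians ran from 194 to 204. The table has no detection calls. Of its 22810 probe sets, 64 were array controls and were left out, leaving 22746. Arrays have no read depth, so their number limits the precision.

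Each array was scaled to the mean 2% trimmed mean (factors from 0.99955 to 1.0005), values under the 20th percentile of all values (20 signal units) were set to that floor, and log2 was taken. The upper 60% of probe sets by mean signal over all arrays were tested, which gave 13647 probe sets with a mean signal of at least 113; 0.0173% of their values lay at the floor. Fold changes of transcripts near the floor are understated. Gene names came from the platform annotation given, updated through the RefSeq gene table of assembly TAIR10.1: 13513 probe sets name 1 gene, of which 13436 were found in that table, 503 name several genes and 8730 are not listed. Of the tested probe sets, 7389 name 1 gene. Probe sets not listed there are given by ID. The probe sets of NIP5;1, NIP6;1, BOR1 and BOR2 are not named in the annotation used, so the mutated genes could not be checked by name.

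Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend; statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p 0.05. The average response to low boron was fitted with genotype as a block (6 residual degrees of freedom). The responses of the 3 genotypes with intact NIP5;1 (wild type, bor1, bor2) and of the 4 nip5;1 genotypes, and their difference, came from a fit with a boron term per class (5 residual degrees of freedom). The classes were compared at each boron level with genotype as a random block (consensus correlation 0.105). The effects of bor1, bor2 and nip6;1 came from an additive fit (7 residual degrees of freedom). Because each group has 1 array, p-values of the boron responses and class comparisons measure the spread between genotypes. The additive fit has no genotype block and counts the arrays of a genotype as independent, so its p-values do not measure that spread alone. The nip6;1 effect rests on a single genotype, so its p-value holds no spread between carrier genotypes. The size of each genotype's response, the SD of its log2 ratios, was compared between classes with an exact permutation test over the 35 splits of 7 genotypes into 4 and 3. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.

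Groups, tests, alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the largest rises and falls past the threshold among probe sets that name 1 gene and moved the same way in every pair of the class (or whose classes do not overlap): up to 10 and 10 for the average and the nip5;1 response, up to 6 and 6 for the intact response, the difference and the comparisons at each boron level, and up to 4 and 4 for the second mutations. Where none passed, the 3 with the smallest p are given as values. The rule also took up to 4 members past the threshold per gene list, all measured members of the boron transport list, and the 5 largest rises and falls of wild type alone.

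Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation as the alternative) and fry where at least 5 members were tested. Of the 34 lists fixed before the data were examined, with 482 entries, only 66 entries had a named probe set and 1 list had 5 tested members. A further 26 lists with 636 entries were drawn up after the annotation was seen and before any test, and 23 of them had 5 tested members. Adjustment ran over the 24 lists of each comparison. For members of the lists fixed beforehand, single genes were also adjusted over the tested members of their own list alone. In a list with 1 tested member, as those of AT3G06450 and HCT, this leaves p unadjusted.

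The fits were tested on simulated data of 13647 probe sets with 50 changed at each size. Of changes of 1 log2 unit, the average fit recovered 96%, the intact fit 90%, the nip5;1 fit 92% and the difference 74%; the comparison at 100 µM recovered 90%, that at 0.3 µM 94%, and the bor1, bor2 and nip6;1 effects 98%, 92% and 80%. Of changes of 0.5 log2 units the average fit recovered 70% and the difference 14%. False calls were 16 of 199 calls in the average fit, 7 of 174 in the intact fit, 9 of 174 in the nip5;1 fit and 11 of 147 for the difference. They were 7 of 177 at 100 µM, 7 of 175 at 0.3 µM, and 17 of 196, 24 of 195 and 8 of 159 for bor1, bor2 and nip6;1. These shares lay above 0.05 in all but the intact fit and the comparisons at each boron level. Alternatives were quantile normalization, no floor, a pseudocount in place of the floor, no filter on dim probe sets, the upper 40% of probe sets, 2 other variance priors, leaving out each genotype with both of its arrays, no genotype block, and only the arrays of a single boron level. The log2 ratio of GAPDH 3′ over 5′ control signals as a covariate was added after seeing the data.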

Results

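Root transcript profiles were recorded on 14 arrays from 7 Arabidopsis genotypes, each after 2 days at 0.3 µM (low) and at 100 µM (sufficient) boron. NIP5;1 is a boric acid channel of the root and NIP6;1 a related channel of the shoot, while BOR1 and BOR2 are borate exporters. In 4 genotypes NIP5;1 was mutated (nip5;1 alone and with bor1, bor2 or nip6;1), called channel mutants here (the last 3 by their second mutation, as in the bor1 double mutant), and in 3 it was intact (wild type, bor1, bor2). The labels describe stunted roots and shoots of the channel mutants under boron limitation. Each genotype and boron level has 1 array, so no genotype has a replicate check of its own. Values are MAS5 intensities, brought to a common scale by the authors, and differences are log2 values with their standard error (SE).

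The ratio of 3′ to 5′ GAPDH control signals, a measure of RNA integrity, was 1.68 ± 0.167 (SD, n = 7) at 0.3 µM and 1.44 ± 0.201 (n = 7) at 100 µM. It was higher at low boron in 5 of the 7 genotypes, by 0.233 ± 0.271 on average (exact two-sided sign-flip p = 0.0938). The bor2 array at 0.3 µM had a median Spearman correlation of 0.975 with the other arrays, against 0.981 to 0.984 for the other arrays at that level. No arrays held identical values.

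Of the boron transport list, 2 of 11 members had a named probe set. AT3G06450, a member of the BOR transporter family, had a signal of 520 ± 106 at 0.3 µM and 523 ± 44.6 at 100 µM (SD, n = 7), an average log2 difference of -0.03 (SE 0.11, limma adjusted p = 0.922). Its signal was lower at 0.3 than at 100 µM in all 3 intact genotypes (-0.34, SE 0.13, adjusted p = 0.515) and had a difference of 0.21 (SE 0.11, adjusted p = 0.35) in the 4 channel mutants, where it ran from -0.09 to 0.57. The difference between the classes was 0.55 (SE 0.17, adjusted p = 0.378). It was the only tested member, and adjusted over the list alone the intact response (limma adjusted p = 0.0238) and the class difference (adjusted p = 0.0087) passed. The intact one was lost without wild type, bor1 or bor2 (up to 0.0892), and the class difference passed whichever genotype was left out (up to 0.0297). At 0.3 µM it was 0.40 (SE 0.12) higher in channel mutants, past the threshold over the list alone (adjusted p = 0.0043, up to 0.0226 with a genotype left out) and not over all probe sets (adjusted p = 0.155). AT5G25430, of the same family, was dim at both levels (20 ± 8.40 and 24.9 ± 12.1, n = 7) and was not tested.

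The average response asked which transcripts differed between 0.3 and 100 µM boron across all 7 genotypes. Low boron raised AT3G53400 17.0-fold (log2 4.09, SE 0.15, n = 7 pairs, adjusted p = 2.1e-07), and CPUORF47, named for a conserved upstream peptide, 8.73-fold (log2 3.13, SE 0.17). The class III peroxidase PRX52 rose by 2.96 log2 units (SE 0.36), with 3 of its arrays at 100 µM at the floor. The defensin-like PDF1.4 rose by 2.41 (SE 0.35), AT5G52390 by 2.59 (SE 0.34), AT4G33720 by 2.5 (SE 0.39), AT1G33790 by 1.68 (SE 0.29) and AT1G30760 by 1.45 (SE 0.19). XTH20, a xyloglucan-modifying enzyme of the cell wall, rose 2.69-fold (log2 1.43, SE 0.15) and the peroxidase AT5G06730 2.49-fold (SE 0.27 in log2).

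Falls were smaller. AT2G43890 was 2.97-fold lower at low boron (log2 -1.57, SE 0.24), AT5G04120 2.77-fold lower (log2 -1.47, SE 0.31) and ATPMEPCRD, a pectin methylesterase, 2.12-fold lower (log2 -1.08, SE 0.15). The plastid-encoded ribosomal protein gene rpl16 fell by 1.01 (SE 0.15) and the photosystem I gene psaJ by 0.75 (SE 0.17). AT5G62420, AT3G45730, AT5G62210, AT1G69080 and AT4G00670 fell by 0.99, 0.91, 0.77, 0.76 and 0.74. Among probe sets without a name here, 251438_s_at (3.27) and 260438_at (2.81) rose most, and 266965_at (-2.24) and 264953_at (-1.88) fell most. For 260438_at and 266965_at 3 of the 7 arrays at the dimmer boron level were at the floor, so their sizes, here and in each class, are understated.

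In all, 514 of 13647 probe sets passed the threshold, 266 higher and 248 lower, of which 51 and 13 differed at least 2-fold, and 259 name 1 gene. The count was 125 without nip5;1, 168 without the bor1 double mutant, 161 without the bor2 double mutant, 202 without the nip6;1 double mutant, 340 without bor1, 333 in the upper 40% of probe sets, 13 with no filter on dim probe sets, and 27 with the GAPDH ratio as a covariate, an alternative chosen after seeing the data. AT3G53400, CPUORF47 and 251438_s_at passed in every one of these settings, and every other gene named for this comparison lost its call without the filter. With the covariate these 3 and XTH20 alone passed of all genes named for the average, and PRX52 (adjusted p = 0.0894), PDF1.4 (0.155) and rpl16 (0.102) were among those lost. With no intensity trend psaJ was lost too (adjusted p = 0.0508), and with a robust variance prior AT5G04120 (0.0719) and 264953_at (0.0877). Of the 20 named genes, 13 passed whichever genotype was left out. AT5G06730 and AT5G04120 were lost without any of the 4 channel mutants (adjusted p up to 0.0866 and 0.0843), AT4G00670 without nip5;1 (0.0502), AT5G62210 without the bor2 double mutant (0.0638), AT5G62420 without nip5;1 or the bor1 double mutant (up to 0.0740), psaJ without any genotype but wild type (up to 0.0851) and AT3G45730 without wild type, bor1, nip5;1, the bor1 double mutant or the bor2 double mutant (up to 0.0803). The probe set 264953_at was lost without wild type, bor1 or any double mutant (up to 0.0894).

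**Figure D1:**
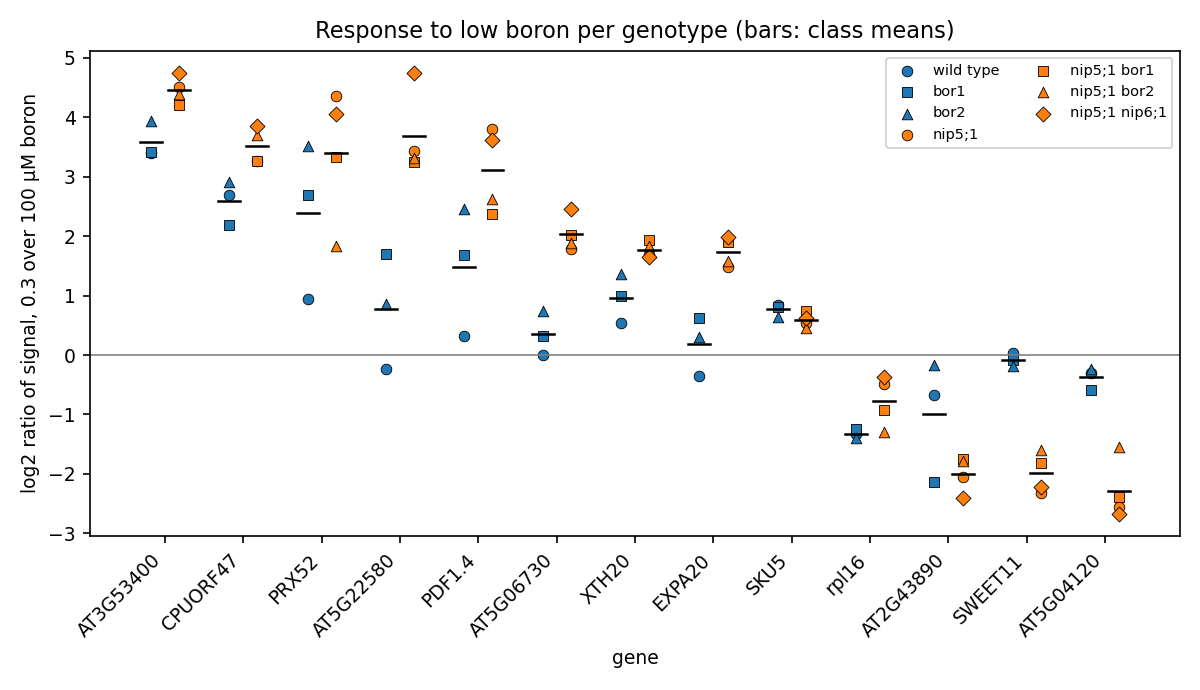
The log2 ratio of signal at 0.3 over 100 µM boron (vertical axis) is plotted for 13 named genes, with 1 point per genotype, blue for the 3 intact and orange for the 4 channel mutants, and black bars for class means. AT3G53400 lies at 3.59 and 4.46 in the 2 classes, SKU5 at 0.77 in the intact class, and SWEET11 at -1.98 in the channel-mutant class.

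Grouped by list, 34 plastid-encoded transcripts were tested for the average response, and 11 fell, 0 rose and 23 did not pass. Of these, rpl16, psaJ, rps19 (-0.71) and rpl14 (-0.70) fell most. The median of the list was -0.36 (camera adjusted p = 2.5e-17, and adjusted p = 0.296 with an estimated correlation, and fry adjusted p = 0.0349). The median signal of these transcripts per array was 583 ± 98.1 at 0.3 µM and 776 ± 112 at 100 µM (SD, n = 7), while the GAPDH ratio moved in the opposite direction, as given above. Of 7 nuclear genes for photosystem proteins and rubisco activase none passed (median -0.24, camera adjusted p = 0.165). Of 40 class III peroxidases, 7 rose and 1 fell (median 0.06, camera adjusted p = 0.0182, and adjusted p = 0.742 with an estimated correlation). PRX52 and AT5G06730 were joined by AT4G36430 (1.14, SE 0.21) and Prx37 (0.75, SE 0.18). Of 7 defensin-like genes, PDF1.4 and LCR69 (0.45) rose and 0 fell (median 0.26, camera adjusted p = 0.0234, and adjusted p = 0.296 with an estimated correlation).

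Cell wall families went both ways in the average response. Of 13 expansins, EXPA20 (1.08, SE 0.25) and EXLA1 (0.44, SE 0.07) rose and EXPB3 (-0.67, SE 0.09) and EXPB1 (-0.61, SE 0.13) fell. Of 9 xyloglucan endotransglucosylases, XTH20 and XTH26 (0.57) rose and XTH21 (-0.58) fell. Neither family shifted as a set (camera adjusted p = 0.636 for each). The xyloglucan list had a median of -0.07 but a mean of 0.15 and an upward camera direction, and in the channel mutants alone a median of -0.01 and a mean of 0.13. Across the lists fixed before the data were examined, 40 members were tested, of which 4 rose and 2 fell adjusted over all probe sets, and 8 and 3 adjusted over the list alone, taking each gene's own list. The risers over all probe sets were XTH20, XTH26, the pectin methylesterase ATPMEPCRB (1.24, SE 0.30) and WRKY6 (0.42, SE 0.09), a transcription factor with a known role in root growth under low boron. The fallers were XTH21 and the wall-sensing receptor kinase THE1 (-0.35, SE 0.07). Of the calcium signalling list 5 members were tested and 0 passed, adjusted over all probe sets or adjusted over the list alone (median -0.25, camera adjusted p = 0.598). CML38 had a difference of -0.57 (SE 0.38) and CML23 of -0.32 (SE 0.26). EIN3 of the ethylene list (0.18), HCT of the lignin list (0.19), XTH18 (0.29), EXPA18 of the root hair list (0.28) and AT4G17260 of the hypoxia list (-0.24) passed adjusted over the list alone and not over all probe sets, and LHCB4.1 of the shoot list (-0.25) passed neither. Without bor2 LHCB4.1 (-0.40, adjusted p = 0.0343) and CML23 (-0.63, adjusted p = 0.0297) passed over all probe sets. Adjusted over the list alone XTH18 passed whichever genotype was left out. EIN3 did not pass without bor1, the bor1 double mutant or the bor2 double mutant, and HCT not without bor2 or the bor2 double mutant. EXPA18 and AT4G17260 did not pass without wild type or the bor2 double mutant (adjusted p up to 0.0992). With no filter AT4G17260 was lost too (0.0505). Over all probe sets XTH20, EXPB3, EXLA1, PRX52, PDF1.4, rpl16 and rps19 passed whichever genotype was left out, and rpl14 was lost without nip5;1 or the bor2 double mutant (up to 0.0637). EXPB1 was lost without nip5;1, the bor1 double mutant or the nip6;1 double mutant, THE1 without nip5;1, bor1, the bor2 double mutant or the nip6;1 double mutant, XTH21 without any genotype but wild type and XTH26 without any but the nip6;1 double mutant (adjusted p up to 0.126). EXPA20, AT4G36430, Prx37, LCR69, WRKY6 and ATPMEPCRB were lost without any of the 4 channel mutants, EXPA20 also without bor1, and Prx37 and ATPMEPCRB also without bor2 (up to 0.130). With no intensity trend XTH21, EXPA20, Prx37 and ATPMEPCRB did not pass (up to 0.0613), nor did the last 3 with a robust variance prior (up to 0.0887).

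In the 3 genotypes with intact NIP5;1, low boron raised AT3G53400 12.0-fold (log2 3.59, SE 0.13, n = 3 pairs, adjusted p = 4.0e-07), from a mean signal of 143 to 1716. CPUORF47 rose 6.05-fold (log2 2.60, SE 0.17), XTH20 by 0.97 (SE 0.14) and SKU5, a membrane-anchored wall protein of directional root growth, by 0.77 (SE 0.09). The plastid gene rpl16 fell by 1.32 (SE 0.19). Of the probe sets without a name here, 251438_s_at (3.15) and 254971_at (2.86) rose, and 259987_at (-1.61) and 244992_s_at (-1.05) fell. In total 18 probe sets passed, 14 higher and 4 lower, and 1148 had an unadjusted p under 0.05, where 682 would by chance.

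Of the plastid-encoded list, 1 of 34 members fell in the intact class (median -0.45, camera adjusted p = 1.5e-18, and adjusted p = 0.794 with an estimated correlation), and the nuclear photosystem list had a median of 0.07. No other list passed there. Of the 40 members of the lists fixed beforehand 1 rose, XTH20. Adjusted over the list alone 3 rose, XTH20, XTH26 (0.68) and HCT (0.25), and 2 fell, AT3G06450 and THE1 (-0.38), of which XTH20 alone passed whichever genotype was left out. For HCT and AT3G06450, the only tested members of their lists, this p is unadjusted. THE1 was lost without wild type, bor1 or bor2, XTH26 without bor1 or bor2 and with no filter, and HCT without wild type, nip5;1, bor2 or the bor1 double mutant and with quantile normalization, no filter or no intensity trend (adjusted p up to 0.332). The count of 18 was 11 without wild type, bor1, bor2 or nip5;1 (each), 9 without the bor1 double mutant, 5 with no filter and 11 with the GAPDH covariate, and AT3G53400, CPUORF47, 251438_s_at and 254971_at passed whichever genotype was left out. With no filter AT3G53400 and CPUORF47 alone passed of the 9 named, and with no intensity trend XTH20 was lost (adjusted p = 0.0613), as was 259987_at (0.104). XTH20 was lost without bor1, bor2, nip5;1, the bor1 double mutant or the nip6;1 double mutant (adjusted p up to 0.147), SKU5 without wild type or bor1 (up to 0.0866), rpl16 and 244992_s_at without wild type, bor1, bor2, nip5;1 or the bor1 double mutant (up to 0.179 and 0.120), and 259987_at without any of the 7 (up to 0.122).

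In the 4 channel mutants, low boron raised AT3G53400 22.0-fold (log2 4.46, SE 0.12, n = 4 pairs, adjusted p = 8.1e-09), from a mean signal of 160 to 3520. AT5G22580 rose 12.9-fold (log2 3.69, SE 0.29), CPUORF47 11.5-fold (3.52, SE 0.14), PRX52 10.5-fold (3.40, SE 0.44, with 1 of its 4 arrays at 100 µM at the floor) and AT4G33720 9.48-fold (3.25, SE 0.40). PDF1.4 (3.11), AT5G52390 (3.08), AT1G33790 (2.41), AT5G06730 (2.04) and ATPMEPCRB (1.82) also rose. AT5G04120 was 4.91-fold lower (log2 -2.30, SE 0.16), AT2G43890 4.0-fold lower (-2.0, SE 0.25), and SWEET11, a sucrose transporter, 3.96-fold lower (-1.98, SE 0.12). Smaller falls were seen in AT5G62420 (-1.27), ATPMEPCRD (-1.25), the microtubule-associated SP1L5 (-1.17), PR-1-LIKE (-1.08), CCOAMT, a methyltransferase of phenylpropanoid metabolism (-1.08), AT5G38980 (-1.08) and AT1G20823 (-1.01). Without a name here, 260438_at (3.93) and 251438_s_at (3.36) rose, and 266965_at (-3.04) and 247591_at (-2.14) fell.

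In this class 706 probe sets passed, 389 higher and 317 lower, with 94 and 30 of them at least 2-fold. The count was 299 without nip5;1, 273 without the bor1 double mutant, 299 without the nip6;1 double mutant, 422 in the upper 40% of probe sets, 182 with no filter and 223 with the GAPDH covariate. Of the 20 named genes, AT5G62420 was lost without nip5;1 or the nip6;1 double mutant (adjusted p up to 0.0662), PR-1-LIKE without these or the bor1 double mutant (up to 0.136) and CCOAMT without any of the 4 (up to 0.156) and with a robust variance prior (0.0661). With no filter PRX52, AT4G33720, AT5G52390, ATPMEPCRB, AT2G43890, AT5G62420, ATPMEPCRD, PR-1-LIKE, CCOAMT, AT5G38980, AT1G20823 and 247591_at did not pass.

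Class III peroxidases formed the list with the most members past the threshold in the channel-mutant class, with 12 of 40 higher and 3 lower (median 0.18, camera adjusted p = 0.0024, and adjusted p = 0.700 with an estimated correlation). Beside PRX52 and AT5G06730 these included AT4G36430 (1.66, SE 0.16) and Prx37 (1.09, SE 0.18). Of 7 defensin-like genes PDF1.4, PDF2.1 (1.44, SE 0.19) and LCR69 (0.67, SE 0.07) rose (median 0.32, camera adjusted p = 0.0025, and adjusted p = 0.333 with an estimated correlation). Of 13 expansins 3 rose, led by EXPA20 (1.74, SE 0.15) and EXLB1 (0.76), and 3 fell, led by EXPB1 (-0.83) and EXPB3 (-0.82). XTH20 rose by 1.77 (SE 0.12) and XTH21 fell by 0.86 (SE 0.14).

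Of the plastid-encoded transcripts 4 of 34 fell in the channel-mutant class (rpl16 -0.77, psaB -0.64, ndhC -0.48, psbF -0.39), with a list median of -0.31 (camera adjusted p = 1.9e-10, and adjusted p = 0.700 with an estimated correlation). The nuclear photosystem list had a median of -0.46 with 0 of 7 past the threshold (camera adjusted p = 0.0039, and adjusted p = 0.700 with an estimated correlation). The cytochrome P450 list, where CYP71B26 fell (-0.49), had a median of -0.31 (camera adjusted p = 0.0224) and the autophagy list, where APG8A fell (-0.37), a median of -0.12 (0.0254), each with adjusted p = 0.700 with an estimated correlation. Of the 40 members of lists fixed beforehand WRKY6 (0.47), ATPMEPCRB and XTH20 rose and XTH21 fell, and 5 and 3 adjusted over the list alone, the further ones being EXPA18 (0.35), XTH26 (0.49), THE1 (-0.32) and LHCB4.1 (-0.46). Of these THE1 was lost without nip5;1 or the bor2 double mutant, and the other 3 without the bor1 or the bor2 double mutant and with no filter (adjusted p up to 0.159). Without nip5;1 the calls of EXLB1, rpl16, psaB, ndhC, psbF, CYP71B26, APG8A and WRKY6 were lost, as were all of these but EXLB1 without the bor1 double mutant, where EXPB1 was lost too (adjusted p up to 0.217 over all genotypes left out). With no intensity trend WRKY6, CYP71B26, APG8A and psbF did not pass (up to 0.0746), and with no filter XTH20, EXPA20, LCR69, AT4G36430, PDF1.4 and AT5G06730 alone did of the members given here.

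The difference between the 2 responses asked whether transcripts reacted to low boron otherwise in nip5;1 than in intact genotypes. AT5G22580 rose 7.53-fold more in the channel-mutant class (log2 2.91, SE 0.45, n = 4 and 3 pairs, adjusted p = 0.0439), AT3G07540 3.47-fold more (1.8, SE 0.23), AT5G06730 3.22-fold more (1.69, SE 0.23) and the expansin EXPA20 2.92-fold more (1.55, SE 0.23). SWEET11 fell 3.74-fold further (log2 -1.90, SE 0.18, adjusted p = 0.0036) and AT5G04120 3.78-fold further (-1.92, SE 0.24). SWEET11 went from a mean signal of 1351 to 342 in the channel-mutant class and from 901 to 852 in the intact class, where bor2 had 301 at 100 µM and 266 at 0.3 µM. Probe sets 260438_at (2.61) and 266415_at (2.52) had the largest positive differences among those without a name here. The negative ones were 254971_at (-2.66) and 246340_s_at (-2.56). In the intact class 254971_at rose to a signal of 6008 ± 1428 (SD, n = 3) at 0.3 µM, against 1222 ± 360 (n = 4) in the channel-mutant class. At 0.3 and 100 µM it was 1655 and 839 in the bor2 double mutant and 1303 and 1261 in nip5;1. The bor1 double mutant had 1141 and 1176, and the nip6;1 double mutant 789 and 890.

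In total 15 probe sets differed between the classes, 10 with a positive and 5 with a negative difference. The count was 2 without nip5;1, 4 without wild type, 5 without the nip6;1 double mutant, 7 without the bor1 double mutant, 27 without bor2, 46 without the bor2 double mutant, 7 in the upper 40% of probe sets and 0 with no filter. AT5G22580 did not pass with quantile normalization (adjusted p = 0.0562), in the upper 40% of probe sets (0.0549), with no intensity trend (0.0941) or with a robust variance prior (0.139), and EXPA20 not in the upper 40% (0.0529) or with no intensity trend (0.0702). Without nip5;1 SWEET11 and 254971_at alone kept their call among the 10 named. AT5G22580, AT3G07540, AT5G06730, EXPA20 and AT5G04120 were lost also without wild type, the bor1 double mutant or the nip6;1 double mutant (AT5G22580 also without bor2, AT5G06730 also without bor1, adjusted p up to 0.170), 260438_at without wild type or the nip6;1 double mutant and 246340_s_at without wild type (up to 0.0645). Of the lists, photosystem genes (median -0.49, camera adjusted p = 0.0017), cytochrome P450 (-0.20, 0.0363) and defensin-like genes (0.13, 0.0363) differed, with adjusted p = 0.778, 0.778 and 0.726 with an estimated correlation. Class III peroxidases had a median of 0.12 (camera adjusted p = 0.0577). Of the 40 members of lists fixed beforehand none differed. Adjusted over the list alone 3 had a positive difference, AT3G06450, XTH20 (0.81, SE 0.19) and ATPMEPCRB (1.35, SE 0.47), and 1 a negative one, XTH21 (-0.64, SE 0.22). XTH20 kept its call whichever genotype was left out (up to 0.0269), while XTH21 was lost without wild type, nip5;1, bor1 or the nip6;1 double mutant and with no filter. ATPMEPCRB was lost without these genotypes or the bor1 double mutant, and in 5 of the 6 other settings in which it was tested (up to 0.246).

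**Figure D2:**
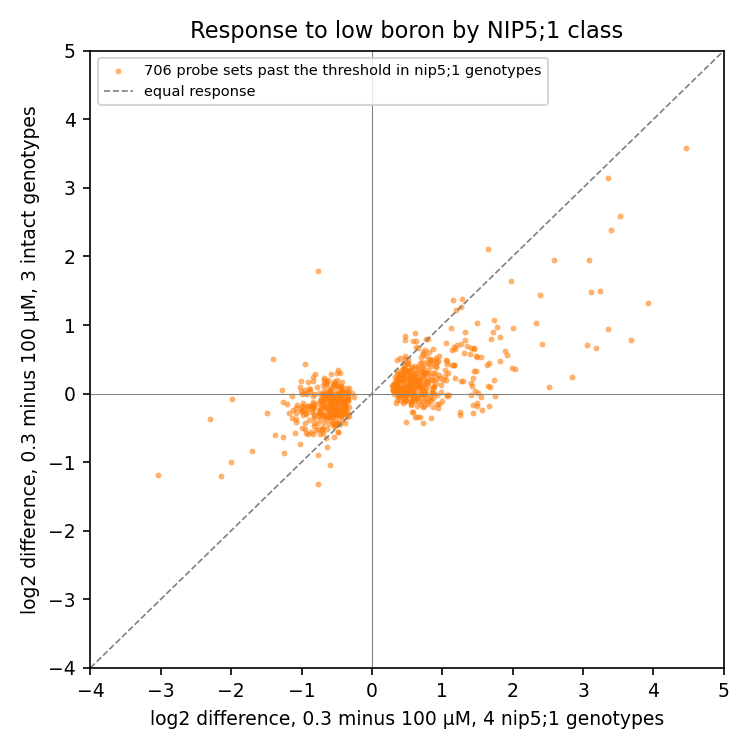
The log2 difference between 0.3 and 100 µM boron in the 3 intact genotypes (vertical axis) is plotted against that in the 4 channel mutants (horizontal axis) for the 706 probe sets past the threshold in the channel-mutant class, 1 point each, with a dashed line of equal response. The same sign was seen in both classes for 557 of them, and the slope among them was 0.34. They were picked for passing in the channel-mutant class, which by itself lowers the slope.

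Of the 706 probe sets called in the channel-mutant class, 557 (78.9%) had the same sign in the intact class, which shares no arrays with it. Their median size was 0.63 in the channel-mutant class and 0.18, taken in the same direction, in the intact class. They were picked for passing in the channel-mutant class, which by itself makes their sizes larger there, so these sizes do not compare the classes. Both classes called 16 probe sets, 12 higher in both, 3 lower in both and 1 in opposite directions, where independent lists would share 0.399 and 0.0929. Both responses came from the same fit with a shared variance estimate per probe set, so the lists are not fully independent. The SD of a genotype's log2 ratios was 0.287 in wild type, 0.301 in bor1 and 0.402 in bor2, and 0.319, 0.421, 0.384 and 0.382 in nip5;1, the bor1 double mutant, the bor2 double mutant and the nip6;1 double mutant. The class means were 0.330 ± 0.0626 (SD, n = 3) and 0.376 ± 0.0424 (n = 4), and the difference of 0.0465 did not pass (exact one-sided permutation p = 0.171, where the smallest possible is 0.0286). It was 0.0824 without bor2 (exact p = 0.0667, the smallest that 15 splits allow), 0.0251 without wild type (exact p = 0.4) and 0.0292 with no filter (exact p = 0.229). Across genes, which are not independent replicates, log2 ratios correlated with Pearson's r of 0.29 to 0.64 between channel mutants (median 0.475, 6 pairs), -0.05 to 0.22 between intact genotypes (0.210, 3 pairs) and 0.05 to 0.44 between the classes (0.241, 12 pairs). The mean r of the channel-mutant pairs was not past the threshold above that of all other pairs (exact one-sided split test p = 0.0571, 35 splits).

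At 100 µM boron the classes were compared to ask whether loss of NIP5;1 alters the root profile under sufficient supply. The 3 named genes with the smallest p were AT5G64250 (log2 -0.44, SE 0.09), the glutathione transferase GSTU27 (-0.44, SE 0.10) and AT3G46280 (-0.84, SE 0.20) in nip5;1 (n = 4) against intact genotypes (n = 3), none past the threshold (adjusted p = 1.00). With limma 0 probe sets passed, and 386 had an unadjusted p under 0.05, where 682 would by chance. With no filter 2 probe sets passed. Plastid-encoded transcripts had a median of -0.25 (camera adjusted p = 3.9e-10), class III peroxidases of -0.15 (0.00043), glutathione transferases of -0.07 (0.0186) and small-subunit ribosomal proteins of 0.08 (9.2e-06), each with adjusted p = 0.611 with an estimated correlation and 0 members past the threshold. None of the 40 members of lists fixed beforehand passed, nor adjusted over the list alone.

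At 0.3 µM boron AT5G22580 was 5.64-fold higher in nip5;1 (n = 4) than in intact genotypes (n = 3), a log2 difference of 2.5 (SE 0.39, adjusted p = 0.0067), PDF1.4 4.11-fold (2.04, SE 0.40) and AT1G33790 3.42-fold (1.77, SE 0.21). AT3G15720 (1.64, SE 0.22), AT3G07540 (1.55, SE 0.22) and AT4G16240 (1.51, SE 0.25) were also higher. AT1G20823 (-1.05), AT4G11210 (-0.95), AT4G11190 (-0.91), AT4G16980 (-0.86), AT4G25250 (-0.86) and XTH21 (-0.85) were lower, each with an SE between 0.17 and 0.23. Without a name here, 250199_at (2.66) and 260438_at (2.48) were higher and 254971_at (-2.32) and 266965_at (-2.15) lower. In total 135 probe sets passed, 97 higher and 38 lower, of which 37 differed at least 2-fold.

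Of 7 defensin-like genes PDF1.4 was higher at 0.3 µM (list camera adjusted p = 0.0321, and adjusted p = 0.545 with an estimated correlation). Medians of -0.50 for photosystem genes (0.02), -0.18 for plastid-encoded transcripts (0.0024), -0.24 for cytochrome P450 (0.0037), -0.24 for glutathione transferases (0.0461) and -0.14 for RALF-like peptides (0.0461) passed with the preset correlation. With an estimated correlation these had adjusted p = 0.701, 0.701, 0.545, 0.572 and 0.545. Among 40 members of lists fixed beforehand XTH20 was higher (0.79, SE 0.15) and XTH21 lower. Adjusted over the list alone 2 were higher, with AT3G06450, and 2 lower, with COR47 of the abscisic acid list (-0.31, SE 0.10), which was lost without wild type or the nip6;1 double mutant (up to 0.157). Over all probe sets XTH20 was lost without wild type, nip5;1, bor1 or the bor1 double mutant (adjusted p up to 0.126) and with no filter. The count of 135 was 26 without wild type, 38 without nip5;1, 33 without the bor1 double mutant, 54 without the nip6;1 double mutant, 246 without bor2, 65 with no filter, 68 in the upper 40% of probe sets and 46 with the 7 arrays of that level alone. AT1G33790, AT3G15720 and AT3G07540 and the 4 unnamed probe sets 250199_at, 260438_at, 254971_at and 266965_at passed whichever genotype was left out. AT5G22580 was lost without wild type (adjusted p = 0.0724), and the other 8 named genes without nip5;1 or the bor1 double mutant, all of them but XTH21 also without wild type, and some also without the remaining genotypes (up to 0.187). With no filter AT5G22580 and these 8 did not pass, PDF1.4 not with no floor (0.0542), and AT4G11190 and AT4G25250 not in the upper 40% or with no intensity trend (up to 0.0612).

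The effects of the second mutations were fitted over both boron levels, with the arrays of a genotype counted as independent. The bor1 and the bor2 arrays come from 2 genotypes each and the nip6;1 arrays from 1. Carriers of bor2 (n = 4 arrays) had 6.34-fold less signal than the others at 1 probe set without a name here, 251254_at (log2 -2.66, SE 0.15, adjusted p = 4.0e-06). Its signal was 83.2 ± 28.3 against 521 ± 36.7 (SD, n = 10), and 1067 probe sets had an unadjusted p under 0.05. Without the bor2 double mutant the bor2 count was 758, and 251254_at passed whichever genotype was left out. For bor1 limma called 0 probe sets (360 with an unadjusted p under 0.05), and 1 without bor1, without bor2 or with no filter. Among probe sets that name 1 gene the smallest p were those of AT4G11290 (0.46, SE 0.08, adjusted p = 0.764), AT5G35940 (-1.12, SE 0.23) and the plastid gene rbcL (-0.64, SE 0.14, adjusted p = 0.948 for both). For nip6;1, present in 2 arrays, limma called 0 (671 with an unadjusted p under 0.05), 2 without bor2 and 6 with no filter. Among probe sets that name 1 gene the smallest p were those of AT1G05430, with a difference of -0.86 (SE 0.12, adjusted p = 0.102), XTH26, with -1.43 (SE 0.24, 0.211), and AT2G39980, with -1.32 (SE 0.24, 0.308).

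**Figure D3:**
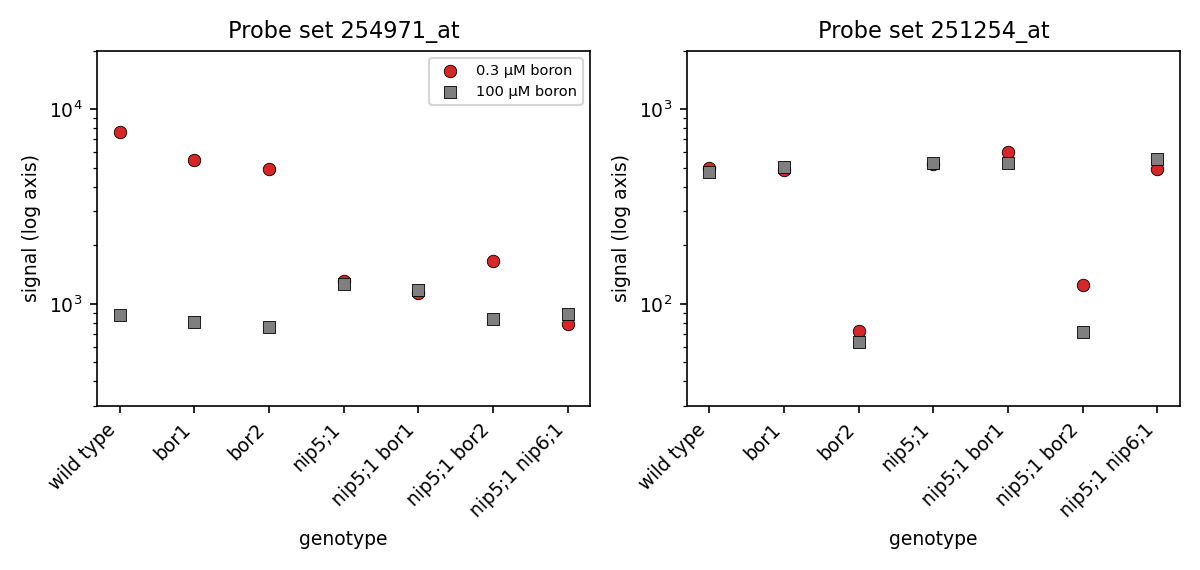
Signal (vertical, log axis) of probe sets 254971_at and 251254_at in the 7 genotypes (horizontal axis) at 0.3 µM (red circles) and 100 µM boron (grey squares), 1 array per point. At 0.3 µM 254971_at averaged 6008 in the intact and 1222 in the channel mutants, and 251254_at averaged 83.2 in the 4 bor2 arrays and 521 in the other 10.

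In wild type alone, compared without replicates or test and only among probe sets that name 1 gene, the 5 highest ratios were as follows. AT3G53400 had a log2 ratio of 3.41 (signal 1735 at 0.3 µM against 163 at 100 µM), CPUORF47 of 2.69, AT4G33720 of 1.48, AT5G52390 of 1.39 and the subtilase SBT4.12 of 1.21. The 5 lowest ratios among these were those of AT5G10040 (at the floor at 0.3 µM against 1023 at 100 µM), AT3G55790 (-3.77), AT2G17850 (-3.69), AT4G10270 (-2.99) and the calmodulin-like CML38 (-1.92).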

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

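The covariate on the ratio of GAPDH 3′ over 5′ control signals and the fits with 2 genotypes in each class were chosen only after the results were seen.

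Single arrays or genotypes stood far from the rest of their group in 4 of the 56 groups of 4 to 7 values examined, where chance marks about 1 in 20 groups, or 2.8 here. The bor2 array at 0.3 µM had a median Spearman correlation of 0.975 with the other arrays. The nip5;1 bor2 array at 100 µM had a ubiquitin 3′ over 5′ ratio of 3.25, against 2.60 to 2.82 in the other genotypes at that level. The response of AT4G00670 to low boron was -1.65 log2 units in nip5;1 bor2 and -0.77 to -0.41 elsewhere. The response of AT5G22580 was 4.75 in nip5;1 nip6;1 and 3.24 to 3.44 in the other nip5;1 genotypes.

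The response to low boron differed between nip5;1 and intact genotypes, by a test of the difference itself, at 15 probe sets. Those named were AT5G22580 (2.91), AT3G07540 (1.8), AT5G06730 (1.69), EXPA20 (1.55), 260438_at (2.61) and 266415_at (2.52) with a higher response in nip5;1 genotypes, and AT5G04120 (-1.92), SWEET11 (-1.90), 254971_at (-2.66) and 246340_s_at (-2.56) with a lower one. Of the 35 splits of the 7 genotypes into 4 and 3, only 1, the real one, gave as many. The highest other count was 11, for wild type, bor1, bor2 and nip5;1 bor2 against the rest. A share of 1 in 35 is the smallest that these splits allow, so they argue against chance without excluding it. For the classes at 0.3 µM only the real split, 1 of 35, reached 135, with 121 as the highest other, so chance cannot be excluded there either. That next highest split put bor2 in the place of nip5;1 bor2 among the nip5;1 genotypes, and a count so close to the real one points to structure among the samples that does not follow NIP5;1 alone. At 100 µM the real count was 0, which all 35 splits reach by construction (highest other 2), so the splits say nothing there.

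For the average response 1 of 64 ways to flip the boron labels within genotypes, the real one, gave 514 probe sets. The highest other count was 63, which argues against chance, but the flips cannot tell boron from another shift shared by all arrays of a level. The splits were too few for a share under 0.05 in the intact class (18 against 1 in the highest other of 4 flips, with 1 reaching 18) and in the nip5;1 class (706 against 0 in the highest other of 8 flips, with 1 reaching 706). They were also too few for the second mutations. All 12 placements reach the 0 of bor1 by construction (highest other 1), and 2 of 12 gave at least the 1 of bor2 (highest other 1).

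Low boron changed 706 probe sets in the nip5;1 genotypes and 18 in the intact ones, a contrast of counts that was not itself tested. With bor2 left out and 2 genotypes in each class, the nip5;1 counts were 97 to 767 and the intact counts 7 to 85 over 6 fits, at least 7.14 times apart in the same fit, while the 12 fits of that size with bor2 gave 27 to 193 and 4 to 12. Both counts were lower in the fits with bor2, but the contrast stayed without it, so its outlying array is not the whole cause, and with 1 nip5;1 genotype left out the lowest count was 273, with 9 in the intact class of the same fit, which argues against the class sizes of 3 and 4. A stronger reaction to low boron where NIP5;1 is mutated may underlie the contrast, as a hypothesis found in and tested on the same data. With the GAPDH ratio as a covariate the counts were 223 and 11. Without the covariate the difference in the size of the responses was 0.0465 (exact permutation p = 0.171, one-sided). It was 0.0824 without bor2 and 0.0251 without wild type, so single genotypes moved it by more than 1.5 times.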

How the results depend on the processing

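The covariate on the GAPDH ratio was chosen after seeing the data, the other alternatives before. Counts of probe sets past the threshold moved by more than 1.5 times under these. With no filter on dim probe sets they were 13 for the average response, 5 intact, 182 nip5;1, 0 for the difference, 2 for nip5;1 at 100 µM, 65 at 0.3 µM, 1 for bor1 and 6 for nip6;1. In the upper 40% of probe sets they were 333 for the average, 422 for nip5;1, 7 for the difference and 68 at 0.3 µM. With only the arrays of 0.3 µM the count there was 46. With the covariate they were 27, 11 and 223 for the average, intact and nip5;1 responses, and 15 for the difference, as without it. Under the covariate all 514 probe sets of the average kept their direction, the median size went from 0.48 to 0.46 and the median SE from 0.094 to 0.132. Of the 488 calls lost, 486 had a larger SE, 24 were smaller by over 1.5 times (as XTH21, from -0.58 to -0.35) and 182 were at least as large. Fewer or more probe sets tested change both the adjustment and the shared variance, and beyond that the cause was not tested.

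With each genotype left out in turn, the lowest and highest counts were 125 to 601 (average), 9 to 18 (intact), 273 to 945 (nip5;1), 2 to 46 (difference), 0 to 0 (nip5;1 at 100 µM), 26 to 246 (at 0.3 µM), 0 to 1 (bor1), 1 to 758 (bor2) and 0 to 2 (nip6;1). The nip6;1 effect could not be fitted without its only carrier. AT3G06450, which did not pass, ran from -0.13 to 0.032, turning sign without wild type, bor1 or bor2. Its signal was lower at 0.3 than at 100 µM in each of these, so leaving any of them out raises the average.

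All genes named past the threshold kept their direction in every leave-out. In the leave-outs 19 of 49 named for the average kept their call each time, 4 of 9 for intact, 34 of 54 for nip5;1, 2 of 10 for the difference, 7 of 17 at 0.3 µM and 1 of 1 for bor2. In the other planned settings 3, 2, 19, 0, 7 and 1 did, and with the covariate 4 of 49 for the average, 5 of 9 for intact, 31 of 54 for nip5;1 and 10 of 10 for the difference. Quantile normalization, no floor, a pseudocount, no trend, a robust prior and no genotype block (355 for the average) left the counts within 1.5 times, but not every call, as for AT5G22580 and EXPA20 in the difference. The median log2 difference of all tested probe sets lay within 0.03 of 0 in the boron and class comparisons, as reported and with each other normalization, floor, filter or variance prior. No paired analysis by replicate was possible because every group has 1 array, numbered 1. Signal at the floor on 1 to 3 arrays of a boron level limits the folds of PRX52, PDF1.4, 260438_at and 266965_at.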

Other observations

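The tests on less green tissue and on the probe sets 251254_at and 254971_at, and the GAPDH covariate, were chosen only after the results were seen.

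Further members of gene families passed in the nip5;1 response to low boron. The nitrate and peptide transporter family member AT1G59740 rose by 0.87 log2 units, the cellulose synthase-like CSLC12 by 0.73, the glycosyltransferase UGT85A2 by 0.60, BGLU15 of the beta-glucosidases by 0.61 and AT2G31110 of the TBL family by 0.79. UGT74F1 fell by 0.82, TBL38 by 0.63 and the MADS-box gene AGL19 by 0.57. UGT74F1 was lost without nip5;1, nip5;1 bor1 or nip5;1 nip6;1 (adjusted p up to 0.131), AGL19 without any of the double mutants (up to 0.110) and CSLC12 without wild type or any nip5;1 genotype (up to 0.158). With no filter these 3, TBL38 and AT1G59740 did not pass. The difference between the classes was not past the threshold for these genes.

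Genes that were bright in wild type at 100 µM varied between genotypes at that level. AT5G10040 had signals of 1023 in wild type and 954 in nip5;1 bor2, 164 in bor1 and 183 in nip5;1 bor1, and 23.0, 20 and 75.4 in nip5;1, bor2 and nip5;1 nip6;1. AT2G17850 had 541 and 612 in wild type and nip5;1 bor2, and 27.9 to 132 in the others, and AT4G10270 had 388 and 583, and 73.9 to 189.

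Plastid-encoded transcripts were lower at 0.3 µM as a list, with a median of -0.36 in the average response. Less green tissue would lower nuclear photosystem genes too, and their median was -0.24 in the average response, and -0.46 in the nip5;1 genotypes, where that of the plastid-encoded list was -0.31, so it may account for the pattern there. In the intact genotypes the nuclear median was 0.072 against -0.45, so the lists did not move together in that class. The SE of that nuclear median, 0.0905, was taken over the genes of the list and holds no spread between genotypes. It therefore cannot decide on less green tissue there. RNA integrity read from the GAPDH ratio would take up the shift, yet the median with the covariate was -0.42, or 116% of its size, and 1 of 64 flips of the boron labels, the real one, lay as far from 0 (highest other size 0.311), against swings between arrays. The actin and ubiquitin ratios were not tried as covariates. Less green tissue stays open for the average response and for each class, and no list passed with an estimated correlation.

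Among probe sets without a name here, 251254_at was picked as the 1 called for bor2 and 254971_at for its class difference, so the gaps between carriers and other arrays restate what they were picked for. For 251254_at the nearest arrays lay 1.93 log2 units apart, and for 254971_at 1.57 apart at 0.3 µM. At 100 µM the gap of 254971_at was -0.74. The 3 intact arrays stood at 757 to 875 there and the 4 nip5;1 arrays at 839 to 1261, all far above the floor. These values argue against a transcript lost in the nip5;1 carriers at both levels. Whether the signal at 100 µM comes from the transcript that rose at 0.3 µM was not tested. Whether 251254_at reads a transcript lost in the bor2 carriers stays open. At 0.3 µM 3 probe sets had every nip5;1 carrier at least 2-fold below the others, and over both levels 1 did for bor2 and 0 for bor1 and for nip6;1.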
